A study of Mus musculus with 4 samples.

How the data were processed

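RNA was measured by sequencing in 4 libraries of telencephalic tissue from mouse embryos at embryonic day 13.5, of the mixed strain B6D2F2. The labels conflict on the tissue: titles and tissue fields give telencephalic tissue and the extraction protocol gives cerebral cortex, so ventral, choroid plexus and diencephalon genes may come from inside or outside the intended piece. Per the labels, KO26F and KO23M carried no intact Tcf20 allele and WT25F was wild type. The labels disagree about the fourth library, WT22M: its title calls it wild type and its genotype field calls it heterozygous. The libraries were made from total RNA with a TruSeq kit, per the labels' protocols. Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.0 are named in the submitters' processing notes, together with the build mm9. The settings for strand and for reads that match several places are not given in the sources used here. Of 22084 genes in the files, 22039 have their identifier in the GENCODE vM21 annotation of GRCm38, and 20222 of these (91.8%) have the identical chromosome, start and end there, so positions below are given as the files give them, on GRCm38, which differs from the build in the notes.

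The authors deposited 3 tables, each of 1 library against WT25F. Per the file headers, each table holds a whole-number count per gene and library, and these counts are not normalized. Beside each count the authors deposited a normalized value in CPM, the count scaled to the library total, with a count of 0 written as 0.5 counts. The authors' deposited log2 fold change is the log2 ratio of these normalized values. The deposited tables also give a p-value and an adjusted p-value per gene, from a test that is not given in the sources used here. The deposited mark of significance matches an adjusted p under 0.05 with an absolute log2 fold change of at least 1 for all genes of the 3 tables.

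Each table lists a gene if it has a count of at least 1 in both libraries, or of at least 5 in either with 0 in the other, a rule that 0 genes broke. The tables were joined by gene identifier, which gave 22084 genes, 19626 of them in all 3 tables. A gene missing from a table was set to a count of 0. Where WT25F was at 0, the true count of such a gene may lie between 0 and 4; this concerns 141 genes in KO26F, 183 in KO23M and 158 in WT22M. The joined totals were 18127024 counts in KO26F, 18509743 in KO23M, 17944649 in WT25F and 17791641 in WT22M, so 3 counts, the limit that a count of 0 allows, correspond to 0.162 to 0.169 CPM. Intervals at the 95% level and floors cover counting error only.

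The main comparison set the 2 knockout-labelled libraries against WT25F and WT22M, which carry at least 1 wild-type allele under either label and are called carriers here. Counts were tested with the quasi-likelihood test of edgeR 4.0.16 (robust fit, TMM normalization, filterByExpr on the 2 arms, Benjamini-Hochberg threshold 0.05), which left 16252 genes. KO against WT25F and WT22M against WT25F came from a fit with 3 groups, in which the spread comes from the 2 KO libraries alone and the lone libraries are assumed to vary like them. The labels do not say that the libraries came from separate litters, so p-values measure the spread between these samples. Gene lists fixed before the data were examined were tested with camera of limma 3.58.1 (preset correlation 0.01, and again with an estimated correlation) and with fry, adjusted over 30 lists; 595 of 610 list symbols were found in the files.

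Genes are named by a rule fixed at the same time. It takes Tcf20 and a short list of genes tied to it or to DNA demethylation, and the 10 higher and 10 lower genes with the largest absolute log2 fold change past the threshold, with a mean log2 CPM of at least 1 and both KO libraries on the same side of both carriers. It also takes up to 4 members with the smallest raw p in each list described, the 5 higher and 5 lower genes of WT22M against WT25F, and 5 sex-linked genes. Genes named outside this rule were chosen after their values were seen, also where this is not repeated. This holds for H2-D1, Gbx2, Hba-a1 and the named choroid plexus genes.

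The alternatives were RLE size factors, DESeq2 1.42.0, limma voom, no filter, a filter of at least 1 CPM in 2 libraries, the title letter as a block, genes on X and Y left out, and each library left out in turn. A pseudocount alternative for normalized values did not apply, since the files hold counts. The scripts were tested on simulated data with 200 of 16252 genes changed. For KO against carriers, 29.9% of genes changed by 1.5-fold, 65.7% by 2-fold and 95.5% by 4-fold were called, with 6 unchanged genes called. For KO against WT25F these shares were 26.9%, 61.2% and 86.4%, and for WT22M against WT25F 2.99%, 49.3% and 81.8%. R 4.3.3 and Python 3.11.15 were used.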

Results

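Messenger RNA was counted per gene in 4 libraries of embryonic mouse telencephalon, the part of the forebrain that forms the cortex and the basal ganglia. The series asks how loss of Tcf20, a nuclear protein related to Rai1, affects the formation of neurons. There were 2 knockout-labelled libraries (KO26F and KO23M), 1 wild type (WT25F) and 1 library whose labels conflict (WT22M). Depth was even, from 17791641 to 18509743 counts, and between 20626 and 21811 genes had at least 1 count. The letters in the titles matched sex-linked genes: Xist, which silences an X chromosome in females, stood at 519 CPM in KO26F and 450 in WT25F, against 0.0540 in KO23M and 0.169 in WT22M. Ddx3y, Uty, Kdm5d and Eif2s3y, all on the Y chromosome, had 0 counts in KO26F and WT25F, and Kdm5d reached 33.7 CPM in KO23M and 34.9 in WT22M.

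Tcf20 itself (ENSMUSG00000041852, chromosome 15, 82808629 to 82912134, minus strand) was only slightly lower in the knockout-labelled libraries. It stood at 98.6 CPM in KO26F (95% counting interval 94.1 to 103) and 104 in KO23M (99.2 to 109), against 118 in WT25F (113 to 124) and 111 in WT22M (106 to 116). The log2 fold change was -0.18 (SE 0.10), which did not pass the threshold (edgeR adjusted p = 1). The part of the gene that was deleted is not given in the sources used here, and counts over the whole gene include reads from outside it, so these values do not check the genotype labels. Tcf4, a transcription factor of neural progenitors, stood at 259 ± 18.8 CPM (SD, n = 2) in the KO libraries and 253 ± 13.6 (SD, n = 2) in the carriers. Tdg, a glycosylase that removes oxidized methylcytosine from DNA, was at 22.7 CPM in KO26F, 78.5 in KO23M, 138 in WT25F and 21.4 in WT22M, so the libraries of each arm lay farther apart than the arms (log2 fold change -0.64, SE 1.46, edgeR adjusted p = 1). Tet1, Tet2, Tet3, Dnmt1, Dnmt3a, Dnmt3b, Rai1 and Phf14 lay between 0.00 (Dnmt1) and 0.31 (Tet2) on the log2 scale and none passed.

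Between the knockout-labelled libraries and the carriers, 10 genes passed the threshold, 5 higher and 5 lower. Slc7a11, the cystine and glutamate exchanger of the cell membrane (ENSMUSG00000027737, chromosome 3, 49892526 to 50443614), rose from 4.75 ± 1.08 CPM (SD, n = 2) in carriers to 22.1 ± 0.406 (SD, n = 2), a log2 fold change of 2.22 (SE 0.19, edgeR adjusted p = 6.5e-08). AI506816, a processed transcript on chromosome 5 (23698296 to 23712667), fell from 59.2 ± 4.63 CPM to 0.384 ± 0.237 (log2 fold change -7.25, SE 0.23, edgeR adjusted p = 3.5e-16), with 14 counts in the KO libraries together against 2116 in the carriers. Rint1, a vesicle transport gene that starts at 23787711 on the same chromosome, was lower by 0.91 on the log2 scale, from 17.8 ± 0.0111 to 9.50 ± 0.681 CPM (edgeR adjusted p = 0.0278). Rpl3, a protein of the large ribosomal subunit on chromosome 15 (80077794 to 80091868), fell from 757 ± 120 to 455 ± 28.3 CPM (log2 fold change -0.74, SE 0.11, edgeR adjusted p = 0.00274), and Sfi1, a centrosome gene, from 87.7 ± 1.96 to 54.9 ± 7.87 CPM (log2 fold change -0.67, SE 0.12, adjusted p = 0.0154).

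The other higher genes were 3 processed pseudogenes and a long noncoding RNA. CT571252.1, which matches alpha-tubulin Tuba1a in the authors' protein annotation, had 851 counts in the KO libraries and 3 in the carriers, a ratio of 277 (95% counting interval 94.4 to 1344, edgeR adjusted p = 2.55e-14). AC154767.3 and Gm14150, which match Tuba1b, rose by 3.11 (SE 0.14, adjusted p = 1.02e-12) and 2.59 (SE 0.17, adjusted p = 9.75e-09) on the log2 scale, and Gm26917, the noncoding RNA, by 0.62 (SE 0.12, edgeR adjusted p = 0.0350). Pisd-ps2, a transcribed pseudogene, fell by 1.07 on the log2 scale (SE 0.18, adjusted p = 0.0350). Rpl3 and the tubulin pseudogenes share their protein description with other genes, between which reads can be split, and Pisd-ps2 is itself a pseudogene, so their values are uncertain. Rpl3-ps1, a copy of Rpl3 named after its values were seen, went the other way, at 281 CPM in KO26F, 350 in KO23M, 32 in WT25F and 180 in WT22M. At an unadjusted p under 0.05 there were 464 genes, against 813 that chance would give. With the title letter as a block the test called 123 genes, among them the same 10, and 63 of the 123 changed by under 1.5-fold. Leaving out a library gave 42 calls without KO26F, 110 without KO23M, 96 without WT25F and 57 without WT22M.

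**Figure D1:**
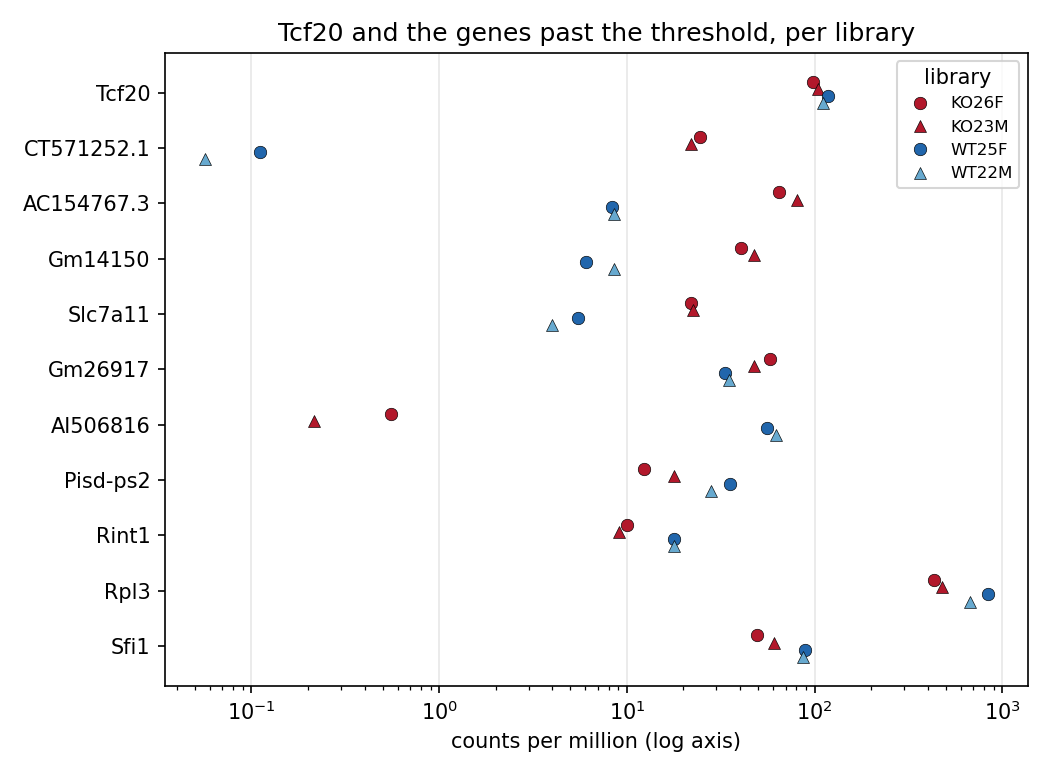
CPM on a log axis for Tcf20 and the 10 genes past the threshold, 1 point per library; circles are libraries with the letter F and triangles those with M, red for knockout-labelled, dark blue for WT25F and light blue for WT22M. Tcf20 spans only 98.6 to 118 CPM, while AI506816 lies under 1 CPM in both KO libraries and at 55.9 and 62.5 in the carriers.

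The gene lists ask whether progenitors, neurons or other cells differed as groups. Of 30 lists, 16 passed with the preset correlation, 8 higher and 8 lower; 0 passed with an estimated correlation, where the lowest adjusted p was 0.412, and 0 with fry. Genes of dividing cells were higher: 20 of 20 measured G2 and M phase genes were on the higher side (median log2 fold change 0.15, camera adjusted p = 6.33e-07, adjusted p = 0.412 with an estimated correlation), such as Mki67 at 161 ± 20.2 against 135 ± 15.1 CPM (SD, n = 2). Of S phase genes 19 of 20 were higher (median 0.11, adjusted p = 2.12e-06, adjusted p = 0.442 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, was at 132 ± 6.77 against 101 ± 7.82 CPM and was the 1 member that passed adjusted over the list alone. Intermediate progenitor genes were higher in 13 of 14 (median 0.15, adjusted p = 1.56e-05, adjusted p = 0.412 with an estimated correlation), with Tmem158 at a log2 fold change of 0.32 and Mfng at 0.28. Genes of ventral GABAergic cells were higher in 21 of 27 (median 0.17, adjusted p = 1.71e-05, adjusted p = 0.412 with an estimated correlation), with Dlx2 at 0.30 and Lhx8 at 0.48. None of these members passed over all genes tested in the fit without a block. With the title letter as a block, which leaves 1 residual degree of freedom, Rrm2 (edgeR adjusted p = 5.43e-05), Dlx2 (0.000533), Lhx8 (0.0133), Mfng (0.0170), Mki67 (0.0274) and Tmem158 (0.0340) passed.

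General neuronal genes were slightly lower in 17 of 20 (median -0.06, camera adjusted p = 0.0113, adjusted p = 0.442 with an estimated correlation), with Gap43 at -0.19. So were 21 of 24 synapse genes (median -0.07, adjusted p = 0.00524, adjusted p = 0.412 with an estimated correlation), with Grin2b at -0.18. Excitatory neuron genes (median 0.00, 11 of 20 higher) and radial glia genes (median 0.09, 13 of 20 higher) did not pass, and neither did the autism gene list (median 0.01). Mesenchyme and meninges genes were lower in 17 of 20 (median -0.21, adjusted p = 1.22e-06, adjusted p = 0.442 with an estimated correlation), and 4 passed adjusted over the list alone, Col1a2 (log2 fold change -0.42), Aldh1a2 (-0.65), Col1a1 (-0.36) and Col6a1 (-0.40). With the title letter as a block Col1a2 (edgeR adjusted p = 2.08e-05), Col1a1 (0.00213) and Aldh1a2 (0.0196) passed over all genes. So did Vtn of the endothelium and pericyte list (lower, 0.0102) and, against the direction of most radial glia genes, Tnc (lower, 0.0101). Microglia and macrophage genes were lower in 16 of 17 (median -0.31, adjusted p = 1.39e-06, adjusted p = 0.412 with an estimated correlation) and endothelium and pericyte genes in 17 of 18 (median -0.15, adjusted p = 1.56e-05, adjusted p = 0.412 with an estimated correlation). Without WT25F, 7 lists passed in place of 16.

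Smaller groups passed with the preset correlation as well. Notch pathway genes, which hold progenitors back from becoming neurons, were higher in 13 of 17 (median 0.09, camera adjusted p = 0.0132, adjusted p = 0.442 with an estimated correlation). Genes of the amino acid and unfolded protein response were higher in 12 of 18 (median 0.03, adjusted p = 0.0175, adjusted p = 0.442 with an estimated correlation), but this rested on Slc7a11: without it the list did not pass (17 genes, median 0.03, camera adjusted p = 0.255). Psat1 passed with the title letter as a block (higher, edgeR adjusted p = 0.0414). Interferon response genes were lower in 12 of 18 (median -0.29, camera adjusted p = 0.000235, adjusted p = 0.442 with an estimated correlation). H2-D1 was the only member that passed under the block (lower, edgeR adjusted p = 9.08e-11). It lies on chromosome 17, where H2-T22, a related gene outside the list, was called higher under the block (log2 fold change 1.67). Cajal-Retzius genes, of the earliest cortical neurons, were lower in 7 of 10 (median -0.16, adjusted p = 0.0380, adjusted p = 0.561 with an estimated correlation). Erythroid genes passed as higher (adjusted p = 0.0297, adjusted p = 0.558 with an estimated correlation). Their median was 0.00 and 5 of 11 were lower, with a mean of 0.17. Hba-x passed under the block (higher, edgeR adjusted p = 3.46e-05). Hem and choroid plexus genes (15 of 20 higher, median 0.24, adjusted p = 0.00412, adjusted p = 0.561 with an estimated correlation) and diencephalon genes (7 of 7 lower, median -0.97, adjusted p = 0.000235, adjusted p = 0.442 with an estimated correlation) also passed. The carriers differed from each other in several of these lists. For WT22M against WT25F, microglia (median 0.22, camera adjusted p = 0.0143) and interferon genes (0.25, 0.0119) were higher, as were S phase genes (0.16, 0.00438). Erythroid (-0.58, 5.09e-08), diencephalon (-1.25, 1.67e-05) and general neuronal genes (-0.08, 0.0376) were lower. All 6 of these lists had adjusted p = 0.812 with an estimated correlation. Against WT25F alone, the KO libraries did not pass for microglia (camera adjusted p = 0.0611), interferon (0.136), choroid plexus (0.0611) or erythroid genes (0.555), with medians of -0.09 and -0.22 for the last 2. The 14 lists that did not pass had medians from -0.06 to 0.27.

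**Figure D2:**
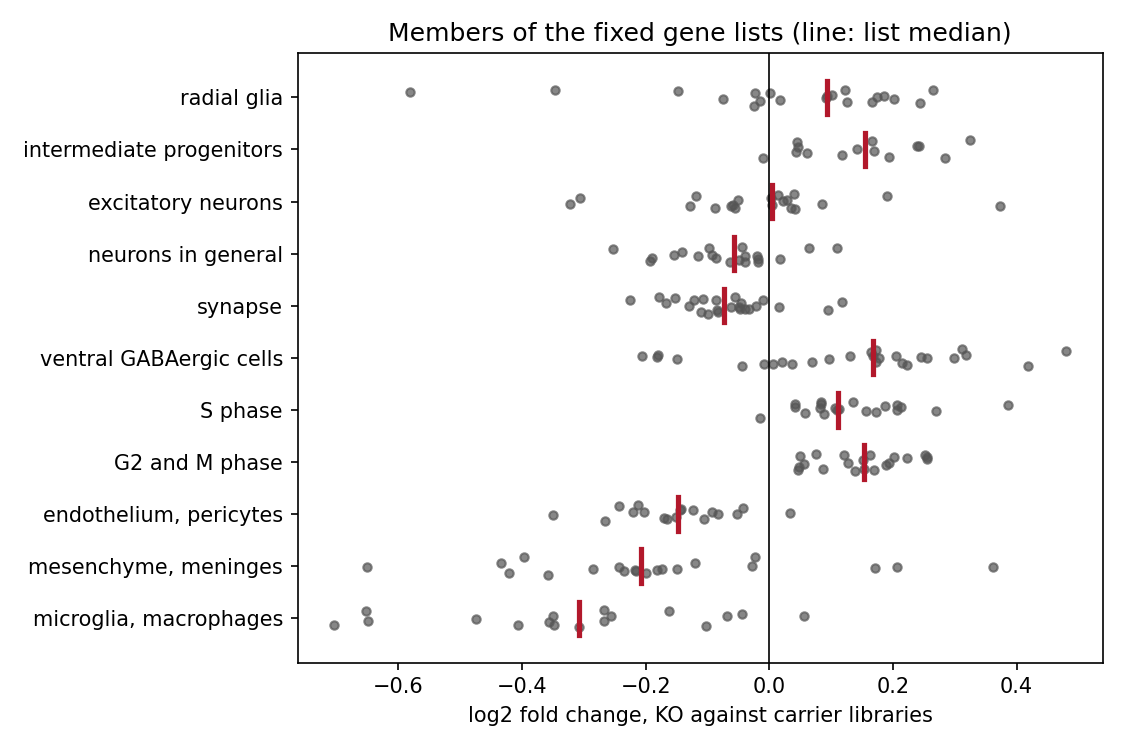
Log2 fold change of the knockout-labelled against the carrier libraries (x axis) for each measured member of 11 fixed gene lists, 1 point per gene with the vertical position spread at random, and a red line at each list's median. The medians of G2 and M phase (0.15) and intermediate progenitors (0.15) lie right of 0 and those of mesenchyme (-0.21) and microglia (-0.31) left of it.

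Against WT25F alone, the comparison that the deposited tables are built on, 56 genes passed, 27 higher and 29 lower in the KO libraries. All 10 genes of the main comparison were among them. WT25F stood apart from the other 3 libraries in genes of the thalamus and diencephalon: 3 of 7 measured list members were lower in KO, Gbx2 (log2 fold change -1.60), Olig3 (-2.24) and Irx1 (-2.03). Tcf7l2, a transcription factor of the thalamus chosen after its values were seen, was at 46.1 CPM in WT25F against 11.1, 9.72 and 7.87 in KO26F, KO23M and WT22M. Of the 56 genes, 30 were also called, in the same direction, between WT22M and WT25F. Unchanged simulated libraries, drawn with the spread of the 2-arm fit, share a control in the same way. Their top 56 and top 116 genes had 9.6 in common on average and at most 15 in 10 simulations. Independent lists would share 0.0482 higher and 0.155 lower genes. Both comparisons use WT25F, which has no replicate, so whatever sets that library apart enters both. The spread of the 2-arm fit takes in the difference between WT22M and WT25F, which lowers the count with that spread. DESeq2 called 23 genes, no filter on low counts left 0 (with 558 at an unadjusted p under 0.05 in the filtered fit), and the spread of the 2-arm fit left 10.

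WT22M and WT25F are 1 library each and also differ in the title letter, so the test compares these libraries and not genotypes. In the 2-arm fit they form 1 arm, so their difference is part of its spread. Few calls with that spread, given at the end of this paragraph, were therefore built in. Here 116 genes passed, 29 higher and 87 lower in WT22M. Genes of the choroid plexus, the tissue that makes cerebrospinal fluid, were lower: 17 of 20 hem and choroid plexus genes were on the lower side (median -0.64, camera adjusted p = 1.43e-26, adjusted p = 0.812 with an estimated correlation) and 6 passed, Ttr, Clic6, Folr1, Kcne2, Sostdc1 and Calml4. Ttr, the thyroid hormone carrier, was at 179 CPM in WT22M against 867 in WT25F, 921 in KO26F and 719 in KO23M. The embryonic globin gene Hbb-y (log2 fold change -0.98) and Hba-a1 (-0.81) were lower as well. Gm13303 and Gm10601, on chromosome 4 at 42025429 and 41809083, had 0 counts in WT22M and were at least 40.7-fold and 19.2-fold lower than in WT25F, with the floor taken as 3 counts in the library. The lower 95% counting limits, which also take in the error of WT25F, were 32.6 and 15.1. Ccl27b, a chemokine gene that starts at 42655251 there, had 1 count against 95, a ratio of 0.0106 (95% counting interval 0.000266 to 0.0606). H2-T23, a histocompatibility gene, had 4 counts against 68, and Gm5900 had 2 against 50. The 5 higher genes with the largest change were the pseudogenes Gm3650 (69 counts against 1, ratio 69.6, interval 12.1 to 2788), Gm7993 (log2 fold change 5.45) and Gm13092 (5.29), the transcript Gm43305 (4.24) and Eif3j2 (3.63). DESeq2 called 33 genes and no filter on low counts 0 (793 at an unadjusted p under 0.05 in the filtered fit); with the spread of the 2-arm fit the count was 0.

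**Figure D3:**
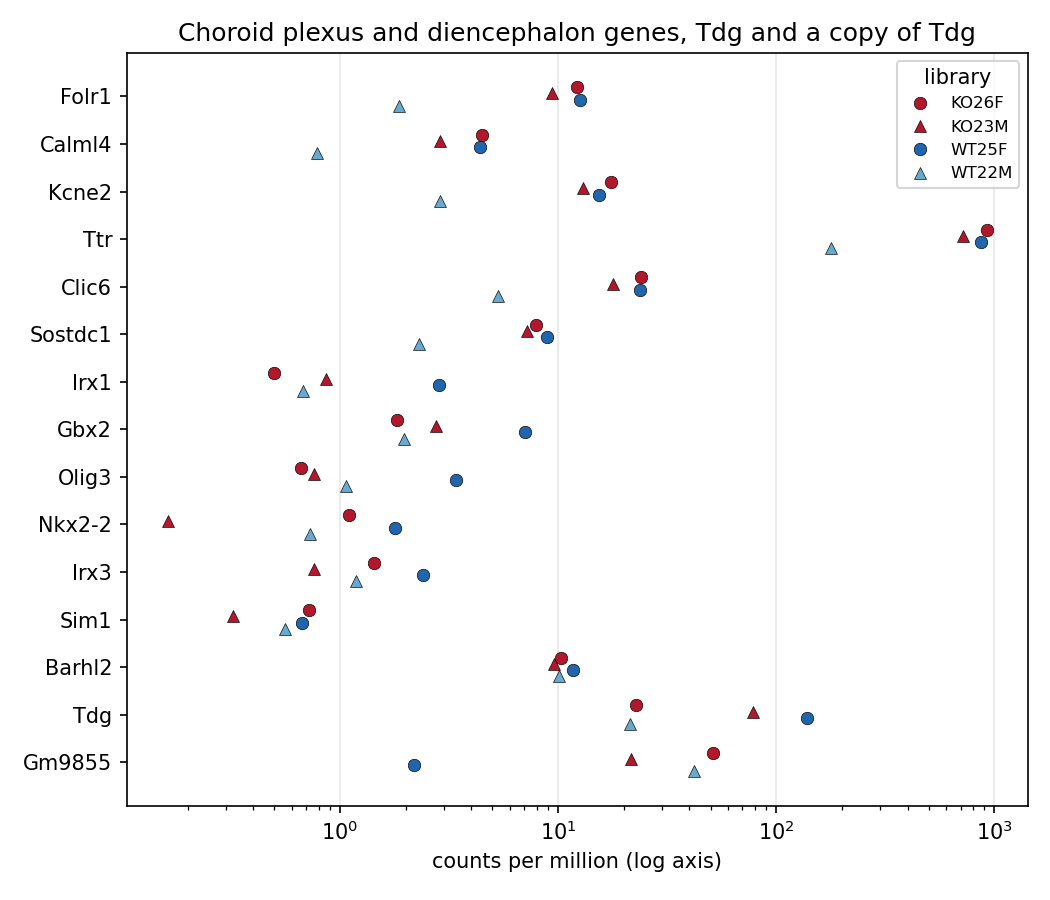
CPM on a log axis, 1 point per library as in the plot of Tcf20 and called genes, for the 6 choroid plexus genes past the threshold, the 7 diencephalon and hindbrain genes measured, Tdg, and Gm9855, a pseudogene copy of Tdg. Ttr lies at 179 in WT22M and from 719 to 921 in the other libraries, while Gbx2 is at 7.02 in WT25F and at most 2.76 elsewhere.

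The authors' deposited tables mark 412 genes for KO26F (197 higher, 215 lower), 603 for KO23M (203 higher, 400 lower) and 752 for WT22M (247 higher, 505 lower), each against WT25F, so the library with a disputed label had the longest list. Of the genes in the authors' deposited tables, 109 were marked in the same direction for both KO libraries, and 71 of these (65.1%) were marked in that direction for WT22M too. Independent lists would share 5.79 genes between the KO tables. Under a single rule of 2-fold and a binomial test with Benjamini-Hochberg adjusted p under 0.05 on the 16252 genes, KO26F and KO23M shared 59 genes, and unchanged simulated libraries compared with a common control shared 64.9 on average. KO26F and WT22M shared 66 (64.9 simulated), while KO23M and WT22M, both with the letter M against a control with F, shared 102 (64.3 simulated, at most 80). For log2 differences from WT25F over 13451 genes, the covariance between KO26F and KO23M was 0.0452 against 0.0447 simulated, between KO26F and WT22M 0.0319 against 0.0450, and between KO23M and WT22M 0.0972 against 0.0448. The correlations across genes were 0.382, 0.256 and 0.651, against 0.497, 0.498 and 0.497 simulated. The simulated libraries were drawn with the spread of the 2-arm fit, which takes in the differences within each arm. That spread raises what simulated libraries share through their control. A value near the simulated one therefore does not show that the KO libraries have nothing more in common.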

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

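The tests of what lies behind these results were chosen after the result was seen. Tdg, the DNA glycosylase, moved in opposite directions in the libraries with the letters F and M. In the F libraries the log2 ratio of KO26F to WT25F was -2.61 (95% counting interval -2.76 to -2.45), and in the M libraries that of KO23M to WT22M was 1.87 (1.71 to 2.04), a difference of 4.48. Dnmt1, the maintenance DNA methyltransferase, differed by -0.16, with 0.09 (0.03 to 0.15) in the F libraries and -0.07 (-0.13 to -0.02) in the M libraries. Neither difference was tested, since each letter has 1 library per arm, and the intervals cover counting error only. Both Dnmt1 ratios lie within the spread between 2 libraries, which is 0.24 on the log2 scale.

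For Tdg, a fall with lower Tcf20 dose stays open: the ratio of 1.87 in the M libraries goes against it, but sets 1 library against 1, lies below the largest difference within an arm (2.69), and drops to 0.66 when counts are summed over the genes with the Tdg description. Reads shared between Tdg and its pseudogenes may account for part of the pattern: Gm9855, a processed pseudogene, was at 51.1, 21.6, 2.17 and 41.8 CPM in KO26F, KO23M, WT25F and WT22M, so it was higher in the libraries with little Tdg (KO26F and WT22M) and lowest in WT25F, where Tdg was highest. Summing the counts of the 4 genes with the Tdg description moved the log2 ratio of WT22M to WT25F from -2.69 to -1.16. That sum lies past the bound of -1 stated for excluding shared reads as the whole cause, but by less than the spread between 2 libraries of 0.24, and the allowance for this spread was added after the value was seen, so the question is left open. A strain variant in this stretch of chromosome 10 also stays open: within 5 Mb of Tdg 7 of 200 genes had an unadjusted p under 0.01 for WT22M against WT25F, and a share of 0.13 of 10000 shifts of the p-values along the genome gave as many.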

How the results depend on the processing

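The settings for protein-coding genes alone, for genes listed in all tables, for the spread of the 2-arm fit, for lists without members called singly and for leaving out libraries in KO against WT25F were chosen after seeing the data; the others were planned. Of the 10 genes called between KO and carriers, 9 kept their direction and call under every setting that tested them. Gm26917 lost its call with no filter, with limma voom, without KO26F and without WT25F, at log2 fold changes from 0.49 to 0.74 over the settings. The count for KO against carriers was 10 with RLE size factors, 11 with DESeq2, 9 with no filter and 9 with limma voom. It rose to 123 with the title letter as a block, which leaves 1 residual degree of freedom. In a run separate from the simulation described above, with 200 of 16252 genes changed, the block called 121 changed and 3 unchanged genes. Without the block these counts were 122 and 3. The block added no calls in that run, unlike the rise from 10 to 123 in the real libraries. The run therefore cannot show whether unchanged genes are part of that rise. Leaving out 1 library, with the lone library of an arm assumed to vary like the other arm, gave from 42 (without KO26F) to 110 (without KO23M) calls. With protein-coding genes alone it was 4, as 4 of the 10 genes are protein-coding.

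KO against WT25F fell from 56 to 23 with DESeq2, 0 with no filter, 35 with protein-coding genes alone and 10 with the spread of the 2-arm fit. WT22M against WT25F fell from 116 to 33 with DESeq2, to 0 with no filter and to 0 with the spread of the 2-arm fit. The 2-arm fit takes WT22M and WT25F as replicates of 1 arm, so their difference is itself part of its spread. Few calls between these libraries were therefore built into that setting, which is no check of their calls. The setting affects KO against WT25F in part. For the other falls the cause was not tested, apart from the fewer genes tested among protein-coding genes. The 16 gene lists past the threshold became 0 with camera with an estimated correlation and 0 with fry, and from 7 (without WT25F) to 19 (without KO26F) when a library was left out; without members called singly 15 passed. No paired analysis by replicate number was possible because the arms share fewer than 2 numbers. The title letters set 1 KO beside 1 carrier library each, which is the pairing that the letter block above fits. The pseudocount alternative did not apply to counts. Depth limits genes of few counts: 3 counts are 0.162 to 0.169 CPM.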

Other observations

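The tests in this part were chosen after the result was seen, except the count of other splits of the libraries. Rpl3 fell in the knockout-labelled libraries while Rpl3-ps1 was higher. A general fall of ribosomal protein genes is argued against by the other 32 list members, whose median log2 fold change was -0.0066. Summed over the 7 genes with the Rpl3 description, the log2 ratio of the knockout to the carrier mean was -0.15, against -0.73 for Rpl3 alone, so reads moving between Rpl3 and its copies may account for most of the change. Why reads would move is open; a strain variant carried along with the targeted allele on chromosome 15 cannot be told apart from chance, since within 10 Mb of Tcf20 4 of 277 genes had an unadjusted p under 0.01 and a share of 0.158 of the shifts gave as many.

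Choroid plexus genes were lower in WT22M than in WT25F. The knockout-labelled libraries lay above WT22M in 15 of 20 list members (median log2 ratio 0.57), which goes against a fall with lower Tcf20 dose. The values also go against the letter M as the whole cause. Gene by gene, the log2 ratio of KO23M to KO26F lay above that of WT22M to WT25F in 16 of 20 members (median difference 0.43, quartiles 0.23 to 1.72). Both points rest on WT22M as a lone library, and the list members may vary together, so they are not replicates. Different amounts of choroid plexus could hide either effect, so neither cause is excluded. A smaller effect of the letter stays open, as KO23M against KO26F had a list median of -0.22 (quartiles -0.39 to -0.03). Different amounts of choroid plexus in the dissected piece stay open too, since the test against 10000 random lists matched on expression shows the shift and not its cause (lowest random median -0.33 against -0.64, giving 0.01%, the smallest share they can give).

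A hypothesis was that strain haplotypes differ between these B6D2F2 embryos, so that genes that differ lie side by side. Between WT22M and WT25F there were 16 pairs of neighbouring protein-coding genes with an unadjusted p under 0.01, against 3.82 in random draws, and 21 against 4.98 among all kinds of genes (share 1e-04 in both, the smallest they can give). Some pairs are clusters of related genes, such as Hbb-bt with Hbb-bs and Xlr3a with Xlr3b, which may vary together for other reasons. Several pairs among all kinds of genes lie in the same stretch of chromosome 4, from Ccl27a (start 41769467) to Ccl27b (start 42655251). The random draws treat these pairs as separate, which they may not be. Between KO and carriers there was 1 pair (share 0.373), and 2 among all kinds of genes (share 0.164). With the title letter as a block there were 7 protein-coding pairs against 6.77 in random draws (share 0.522), and 10 among all kinds of genes (share 0.248). These counts leave the hypothesis open between the arms, since they take only genes next to each other that do not overlap. Within 0.2 Mb of AI506816 on chromosome 5, a place chosen after its values were seen, 4 of 9 tested genes were called with the block, all lower: AI506816 (log2 fold change -7.25), Rint1 (-0.91), 4933427G23Rik (-2.55) and 2700038G22Rik (-0.75). Rint1 ends at 23820369 and 4933427G23Rik starts at 23815618, so these genes overlap, may share reads and are not separate observations. The genes called with the block also gathered on chromosome 17, with 24 of the 121 calls on the autosomes and X against 5.55 expected (share of draws with a chromosome as full 1e-04, the smallest they can give). This was tested after the calls on chromosome 17 had been seen, in a fit with 1 residual degree of freedom, and the calls include related genes such as H2-D1 and H2-T22.

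Another hypothesis was that WT22M carries 1 copy of the stretch of chromosome 15 linked to the targeted allele. On a scale with WT25F at 0 and the knockout mean at 1, the median place of WT22M was 0.502 over 9 genes within 10 Mb of Tcf20. The genes were picked because KO differed from WT25F, which by itself pulls WT22M away from 0: the 186 genes elsewhere had a median of 0.81. Places between 0.25 and 0.75 were more frequent near Tcf20, with 7 of the 9 genes (77.8%) against 53 of the 186 elsewhere (28.5%). The 9 genes lie in the same stretch and rest on WT22M as a lone library. They are not separate observations. The test therefore does not separate a heterozygous from a wild-type WT22M, and the label is left open here.

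There are 3 splits of the 4 libraries into 2 and 2, too few for a share under 0.05. Of these, 2 gave as many calls as the real split, the real one included: 10 genes for the real split, against a highest other count of 41, for the F against the M libraries. The remaining split, KO26F and WT22M against KO23M and WT25F, follows neither the knockout label nor the letter and gave 6. The split of the F against the M libraries follows sex, as read from Xist and the Y genes. Genes on X and Y were kept in these splits, so a difference in sex by itself adds calls to the 41. How many of the 41 lie on X or Y was not counted, so this count does not show a structure of the samples beyond sex.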
